A study of Mus musculus with 6 samples.

How the data were processed

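The data are single-nucleus RNA counts of sorted mouse spinal cord nuclei. The authors deposited 1 matrix of UMI counts per library, with no filter on barcodes (6794880 barcodes listed per library) and no normalization: whole-number counts for 31057 features. These comprised genes with their Ensembl identifiers and 4 added sequences (EGFP, tdTomato, CRE and hSOD1). Per the submitters' processing notes, Cell Ranger, STAR, Seurat and DESeq2 were used with the mm10 genome, and versions are not given in the sources used here, nor is whether intronic reads were counted. Gene positions came from GENCODE vM21 for the same build, which held 30934 of the 31057 identifiers. Where 2 genes overlap, or where near-identical copies such as Calca and Calcb share sequence, the counting can assign their reads to 1 gene or leave them out, so such values are uncertain. Per the labels' protocols, libraries were made with the version 3 chemistry of 10x Genomics from nuclei sorted to a set ratio for the green reporter. Female replicates 3 and 5 and male replicate 4 had a matrix here, and the 3 samples of mixed sex were not analysed here.

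Nuclei were barcodes with at least 1000 UMIs and under 5% mitochondrial UMIs, a limit that 64, 33 and 24 barcodes exceeded (libraries in the order female replicate 3, male replicate 4, female replicate 5). Doublets were scored with scrublet, as implemented in scanpy 1.11.5, at an expected rate of 0.06. Its automatic threshold was kept where it marked at least 0.5% of a library, which held for female replicate 3 (39 removed, 1.55%). In the other libraries it marked 0 and 3 barcodes, so the top 6% of scores were removed (378 and 170). Doublets were thus removed by an uneven rule. Counts were scaled to the library total and log-transformed, 2000 variable genes were scaled within each library (clipped at 10), and 30 principal components and 20 nearest neighbours gave a shared-neighbour graph, clustered by the Leiden method (leidenalg 0.10.2, resolution 1, seed 0). Clusters were named from 18 marker sets. A cluster was called cholinergic-like where Chat was at least 4-fold and Slc5a7 at least 3-fold over the median cluster, and a neuronal cluster with Slc17a6 and the sum of Slc6a5 and Gad2 both at 40 CPM or more was called mixed. Cholinergic nuclei were clustered again, clusters with both Chat and Slc5a7 under 0.25 of the median were set aside (1.29%, 0.68% and 0.39% of nuclei), and a tree of the remaining clusters was divided into 5 branches, each named skeletal, visceral or interneuron by its markers. Skeletal nuclei were clustered again and named alpha-like or gamma-like by marker share, and visceral nuclei were clustered again and kept by number. The Chat and Slc5a7 folds, the 0.25 limit and the number of branches were set after the data were seen. All names rest on these rebuilt clusters, since no annotation by the authors was used here.

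UMI counts were summed per library and class, for classes with at least 20 nuclei, and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. The 3 cholinergic classes of the 3 libraries entered 1 fit, and alpha-like and gamma-like sums another, each with the library as a block, because classes of 1 library come from the same nuclei preparation. Sums of 1 library deviated together from their class means (correlations of 0.25 to 0.667 within libraries, at most -0.004 between libraries). Female and male sums were compared in a fit of 2 against 1 library. Standard errors are the size of the log2 fold change divided by the square root of F, and CPM are given as mean ± SD over 3 libraries. Clusters and tests used the same counts, so folds of the genes that define classes are too large. Two-sided tests were used throughout. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation) and fry, on log2 CPM with a prior count of 2. Of 22 lists, 21 had enough measured members in each comparison: cholinergic transmission, neuropeptides, neuropeptide receptors, monoamine receptors, neurofilaments and axonal cytoskeleton, motor neuron transcription factors, Hox genes, inhibitory transmitter synthesis and transport, GABA and glycine receptors, glutamate receptors, voltage-gated potassium channels, sodium, calcium and HCN channels, nitric oxide and cyclic GMP, neurotrophic factor receptors, axon guidance, cadherins, perineuronal net and matrix, genes linked to amyotrophic lateral sclerosis, the nuclear-encoded respiratory chain, immediate early genes and sex-linked genes. The list of vesicular glutamate transporters had 1 measured member. Over 4 comparisons 84 list tests were made, adjusted within each comparison.

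The designs, markers, lists, alternatives and the rule for named genes were fixed before the data were examined, and what was added later is named as such. The rule took, per comparison of classes, the 10 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, an average log2 CPM of at least 5 and the same sign in all 3 libraries, without class markers and predicted genes, and up to 4 measured members per list with the smallest p. Between sexes it took at most 10 genes by p and the sex-linked genes, and for visceral clusters the 3 genes with the largest log2 fold change, the neuropeptides and Nos1. The text names part of these. Alternatives were DESeq2 1.42.0, relative log expression scaling, no filter on low counts, UMI minimums of 500 and 2000, doublets kept, other Leiden resolutions (0.5 and 2), no library block, leaving out each library, another prior count (0.5), and splitting each UMI between clustering and testing.

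The edgeR fits and list tests were run on simulated class sums with known changes. Doublet scoring, clustering and naming were not, so the rates given here do not cover them. Simulated genes of like expression were given the same spread. For skeletal against visceral nuclei (13616 genes) 83.5% of genes changed 2-fold and 100% of those changed 4-fold were recovered, for skeletal nuclei against interneurons (13659 genes) 67% and 92.9%, for visceral nuclei against interneurons (13699 genes) 70.8% and 93.9%, and for alpha-like against gamma-like nuclei (11312 genes) 76.3% and 100%. Between sexes it was 31.3% and 75.8% in skeletal (13915 genes) and 30.9% and 69.8% in visceral nuclei (14932 genes). False calls made up 2.4% to 8.6% of calls over the 6 comparisons. Few genes were changed in each simulation. For skeletal against visceral nuclei 97 genes were changed 2-fold and 98 were changed 4-fold, and 189 were called. The real fit of these classes called 6401 of 14012 genes. The rates were thus not measured at the share of called genes in the data, and are not error rates of the reported calls. Of 21 simulated lists, camera with the preset correlation called the 1 changed list and 0 of the 20 unchanged lists. The simulated genes varied independently of each other. This therefore cannot show how the list tests behave where the genes of a list vary together. Counts were handled in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9, and figures were drawn with matplotlib 3.10.9.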

Results

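Spinal cord nuclei were profiled from adult mice aged 100 to 150 days. The mice carried Cre recombinase under the control of Chat, the gene of choline acetyltransferase, which makes the transmitter acetylcholine. They also carried a reporter that Cre switches from a red to a green nuclear fluorescent protein. Green nuclei were enriched by fluorescence-activated sorting to a set ratio. Their RNA was counted by droplet-based single-nucleus sequencing with unique molecular identifiers (UMIs), short random tags that let each captured transcript be counted once. Of the 6 samples, 3 were analysed here: female replicates 3 and 5 and male replicate 4. The 3 samples of mixed sex were not analysed here. The libraries held 55039772 (female replicate 3), 72843506 (male replicate 4) and 41740158 (female replicate 5) UMIs. Of these, 77.6%, 84.9% and 70.9% lay in the 2583, 6262 and 2759 barcodes with at least 1000 UMIs. After damaged nuclei and probable doublets were removed, 2480, 5851 and 2565 nuclei remained (10896 in all). They had medians of 14406.5, 8006 and 9147 UMIs and 4601, 3333 and 3471 genes per nucleus, lowest in the male library. That order did not hold within every class named below. Skeletal motor neuron nuclei had medians of 25021.5, 20246 and 17579 UMIs, and visceral ones 21025.5, 11101 and 13688 UMIs. The labels do not say how many animals each library pooled. Gene p-values between classes measure how the class difference varied across these libraries, and those between sexes the spread between libraries. Both kinds of variation may be technical. The p-values of camera and of Fisher's test compare genes with other genes.

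Cholinergic-like nuclei, defined by Chat and by the choline transporter gene Slc5a7, made up 33.3% of nuclei in female replicate 3, 15.02% in male replicate 4 and 37.4% in female replicate 5. Their mean was 28.6% ± 11.9 (SD, n = 3 libraries, 2665 nuclei). Exact binomial 95% intervals, which cover counting error alone, were 31.45% to 35.2%, 14.1% to 16.0% and 35.55% to 39.3%. Because the sort set the ratio of green to other nuclei, this share describes the sort and was not compared between sexes. The other nuclei were excitatory-like neurons with the vesicular glutamate transporter gene Slc17a6 (14.4% ± 4.62, 1703 nuclei) and inhibitory-like neurons with the GABA and glycine genes Gad1, Gad2 and Slc6a5 (12.7% ± 1.71, 1420 nuclei). Neurons of clusters that held both kinds of transmitter gene made up 25.8% ± 8.62 (3144 nuclei). Glia were oligodendrocyte-like (6.52% ± 1.28, 711 nuclei), astrocyte-like (4.85% ± 2.48, 454 nuclei), oligodendrocyte precursor-like (0.92% ± 0.12, 99 nuclei) and ependymal-like (0.43% ± 0.30, 44 nuclei). Clusters that met no naming rule held 5.10% ± 2.77 (574 nuclei). A further 82 nuclei that clustered with cholinergic nuclei but were low in Chat and Slc5a7 were set aside (1.29%, 0.68% and 0.39% of the libraries).

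Within the cholinergic nuclei, visceral-like motor neurons, which innervate autonomic ganglia, were the largest class at 57.4% ± 11.7 (SD, n = 3, 1530 nuclei). Skeletal-like motor neurons, which innervate muscle, made up 28.0% ± 10.8 (749 nuclei), and cholinergic interneuron-like nuclei 14.6% ± 2.73 (386 nuclei). With a UMI minimum of 500 the interneuron share was 7.79% ± 3.98. The skeletal share was 18.2% and 26.2% in the female libraries and 39.6% in the male library. Among skeletal nuclei, those like alpha motor neurons, which drive force-producing muscle fibres, made up 32.7% and 32.3% in the female libraries and 73.6% in the male library (68.6% to 78.1%, exact binomial). The remaining 67.3%, 67.7% and 26.4% resembled gamma motor neurons, which set the sensitivity of muscle spindles. These shares were not tested between sexes, since 1 male library shows no spread between male libraries. Nuclei that differ in size can pass a sort at different rates.

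**Figure D1:**
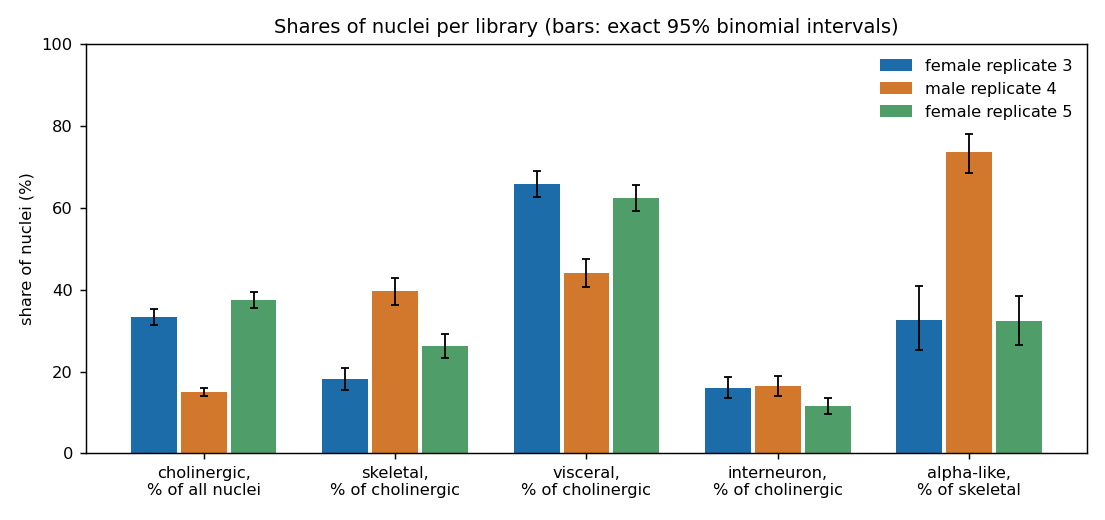
Class shares per library. Bars give the percent of nuclei (y axis, starting at 0) in female replicate 3, male replicate 4 and female replicate 5 for the cholinergic share of all nuclei, the 3 classes as shares of cholinergic nuclei and the alpha-like share of skeletal nuclei. Lines are exact binomial 95% intervals. The male library had the lowest cholinergic share (15.02%) and the highest alpha-like share (73.6%).

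The gene of the vesicular acetylcholine transporter, Slc18a3, had no UMI in any barcode, although cholinergic neurons need it to load acetylcholine into vesicles. Slc18a3 (chromosome 14, 32462438 to 32464850, minus strand, mm10) lies inside Chat (chromosome 14, 32408203 to 32465989, same strand), for which 17401 UMIs were counted. The fixed lists held 10 further genes at 0 UMIs, among them Tubb3, Hoxa3, Hoxa4, Hoxa5, Hoxc6, Hoxc8, Hoxc9, Hoxd4 and Cox4i1. These values say nothing about their expression. Markers of oligodendrocytes and astrocytes were far lower in the cholinergic classes than in glia. The 8 oligodendrocyte markers, among them the myelin gene Mbp, summed to 39.0 to 121.6 CPM (the count of a gene scaled to a fixed sum of all counts) there, against 18402.5 to 22284.9 CPM in oligodendrocyte-like nuclei and 740 to 1497.6 CPM in droplets without a nucleus. Astrocyte markers summed to 18.2 to 93.8 CPM in the cholinergic classes against 8126.8 to 9401.5 CPM in astrocyte-like nuclei. Markers of other neurons were less far apart. Excitatory markers, which include Ebf2, summed to 222.3 to 357.8 CPM in cholinergic interneurons and 100.2 to 197.3 CPM in the motor neuron classes. They were at 1292.4 to 2347.5 CPM in excitatory-like nuclei and 322.5 to 389.6 CPM in droplets without a nucleus. Inhibitory markers, which include Gad1, Gad2 and Slc32a1, summed to 226.9 to 377.1 CPM in interneurons and 11.2 to 47.2 CPM in motor neurons. They were at 762.2 to 964 CPM in inhibitory-like nuclei and 197 to 245.6 CPM in droplets without a nucleus. Markers of microglia and macrophages summed to 37.5 to 60.7 CPM in the cholinergic classes, against 87.7 to 97 CPM in such droplets. The endothelial list was higher in skeletal (44.5 to 60.6 CPM) than in visceral nuclei (7.3 to 10.9 CPM), and it includes Mecom, which is also in the list of motor neuron transcription factors. The visceral markers Nos1 and Cartpt peaked in clusters named interneuron. With libraries pooled, Nos1 was at 987.6 and 994.5 CPM in interneuron clusters 7 and 22, against at most 700 CPM in visceral clusters of that clustering. Cartpt was at 513.4 CPM in interneuron cluster 11, against at most 345.4 CPM in visceral clusters. Zeb2 and Fbn2 were at most 11.6 and 14.5 CPM in interneuron clusters, against at least 15.3 and 21.7 CPM in visceral ones.

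Skeletal and visceral motor neurons, which share acetylcholine as transmitter but differ in target, were compared to find the genes that set them apart. Grin3b, an NMDA-type glutamate receptor subunit, was at 161 ± 36.5 CPM in skeletal and 0.96 ± 0.73 CPM in visceral nuclei (SD, n = 3; log2 fold change 7.71 ± 0.27, SE). Itpr3, an endoplasmic calcium release channel, and Caln1, a calcium-binding protein, were also higher in skeletal nuclei (6.96 ± 0.23 and 5.33 ± 0.11). So were the transcription factor genes Glis3 (7.02 ± 0.34), Rreb1 (5.49 ± 0.24) and Esrrb (5.15 ± 0.23). Further genes on this side were the aldehyde oxidase Aox1 (6.30 ± 0.24), the BMP receptor Bmpr1b (6.17 ± 0.35) and the growth factor Pdgfd (5.18 ± 0.38). Visceral nuclei had more of Baiap3 (-6.52 ± 0.32), which acts in dense-core vesicle traffic, and of the AMPA receptor auxiliary subunit Cacng4 (-6.29 ± 0.25). The NADPH oxidase Nox4 (-5.89 ± 0.35) and the cyclic AMP phosphodiesterase Pde8a (-5.51 ± 0.26) were also higher there, as were the collagen Col8a1 (-5.44 ± 0.27), the G-protein subunit Gnb4 (-5.32 ± 0.25) and the zinc finger gene Zfp804b (-5.12 ± 0.21). Dlk1, which codes for a Notch-like ligand, was at 53.3 ± 13.8 CPM in visceral and 0.25 ± 0.04 CPM in skeletal nuclei. Each of these genes differed in the same direction in all 3 libraries. With edgeR's quasi-likelihood test, 6401 of 14012 genes differed at a Benjamini-Hochberg adjusted p of 0.05, 3301 higher in skeletal and 3100 higher in visceral nuclei. The count was 4195 without the library as a block and 4243 without female replicate 3.

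**Figure D2:**
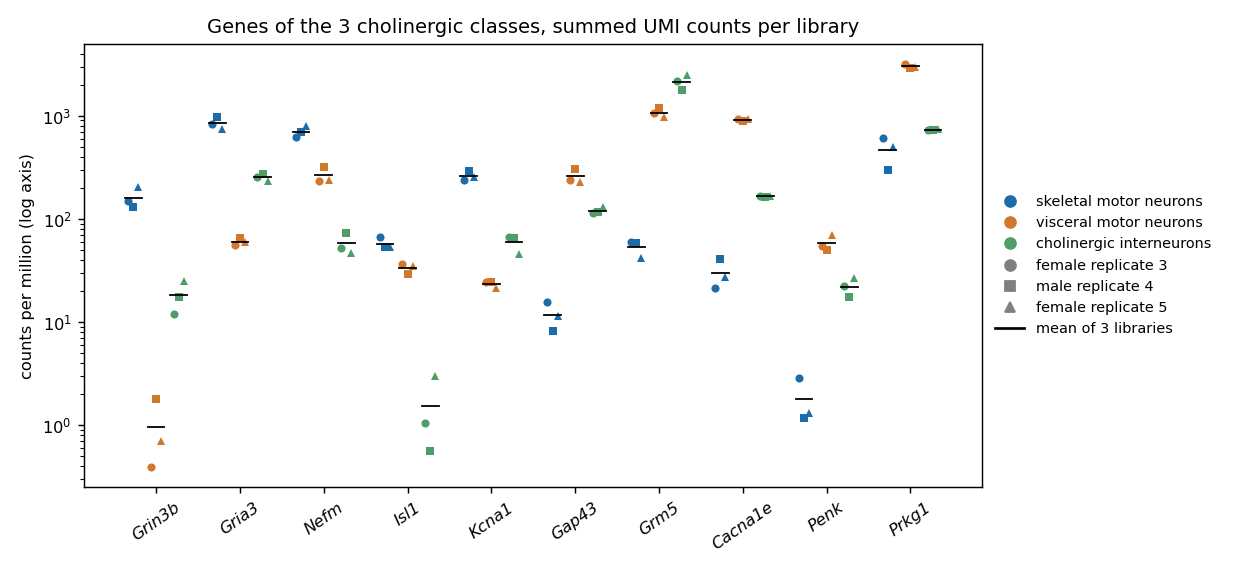
Expression of 10 named genes in the 3 cholinergic classes. The y axis is CPM on a log scale, colour marks the class, marker shape the library and the black line the mean of 3 libraries. In all 3 libraries Grin3b, Gria3 and Kcna1 were higher in skeletal than in visceral nuclei, and Gap43, Grm5, Cacna1e, Penk and Prkg1 were higher in visceral than in skeletal nuclei.

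Ion channels and receptors parted the 2 motor neuron classes gene by gene, with members of each list on either side. Of 33 measured voltage-gated potassium channel genes, 17 were higher in skeletal and 13 in visceral nuclei (30 adjusted over the list alone). Kcna1, an axonal channel, was higher in skeletal (3.48 ± 0.12) and Kcnh7 and Kcnd3 in visceral nuclei (-3.69 ± 0.19 and -2.61 ± 0.16). Among 23 sodium, calcium and HCN channel genes 10 were higher in skeletal and 6 in visceral nuclei (16 adjusted over the list alone). The R-type calcium channel Cacna1e was among the latter (-4.95 ± 0.18, 29.7 ± 9.83 against 915 ± 26.6 CPM). Glutamate receptors numbered 24, with 10 higher in skeletal, among them the AMPA subunit Gria3 (3.81 ± 0.10), and 8 in visceral nuclei (18 adjusted over the list alone), among them the metabotropic receptor Grm5 (-4.34 ± 0.18). The 21 GABA and glycine receptor genes split into 6 higher in skeletal, such as Glra1 (2.79 ± 0.14), and 11 in visceral nuclei, such as Glra2 (-3.45 ± 0.28), with 18 adjusted over the list alone. Receptors for monoamines (14 measured, 4 higher in skeletal and 5 in visceral nuclei, 10 adjusted over the list alone) included the serotonin receptors Htr1d (5.75 ± 0.22), which is also a gamma marker, and Htr2c (-1.88 ± 0.19). Receptors for neuropeptides (16 measured, 4 and 7, 12 adjusted over the list alone) included the NPY receptor Npy1r (-3.85 ± 0.30) and the opioid receptor Oprm1 (-2.65 ± 0.31). The cholinergic list (9 measured) held 2 genes higher in each class (4 adjusted over the list alone), with the muscarinic receptors Chrm2 (1.32 ± 0.13) and Chrm3 (-3.67 ± 0.25) on opposite sides.

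Growth, structure and signalling genes also divided. Of 13 neurofilament and axonal cytoskeleton genes, 9 were higher in skeletal and 3 in visceral nuclei (12 adjusted over the list alone). The neurofilament genes Nefh (2.30 ± 0.15) and Nefm (1.43 ± 0.13) were higher in skeletal nuclei. The growth cone gene Gap43 was higher in visceral nuclei (-4.49 ± 0.21, 11.8 ± 3.76 against 258 ± 41.1 CPM). Neurotrophic factor receptors (14 measured) were higher in skeletal nuclei for 9 genes, among them the GDNF receptor components Ret (2.89 ± 0.16) and Gfra1 (2.41 ± 0.15), and in visceral nuclei for 3 (13 adjusted over the list alone). Neuropeptides (9 measured, including the class markers Calca and Cartpt) held 2 genes higher in skeletal and 4 in visceral nuclei (6 adjusted over the list alone). Among the latter were the enkephalin precursor Penk (-5.05 ± 0.21) and the PACAP precursor Adcyap1 (-4.83 ± 0.34). Nitric oxide and cyclic GMP genes (12 measured, including the class marker Nos1) split into 5 and 4 (9 adjusted over the list alone). The cyclic GMP-dependent kinase Prkg1 (-2.73 ± 0.18) was higher in visceral and the adaptor Nos1ap (2.84 ± 0.15) in skeletal nuclei. Perineuronal net and matrix genes (12 measured, including the class marker Fbn2) split into 7 and 4 (12 adjusted over the list alone), with the proteoglycan Bcan (3.22 ± 0.12) higher in skeletal nuclei. Axon guidance genes split into 7 and 12 of 32 (19 adjusted over the list alone). The ephrin receptor Epha4 (4.01 ± 0.22) was higher in skeletal and the guidance cue Slit1 (-2.49 ± 0.13) in visceral nuclei. Cadherins split into 4 and 4 of 14 (8 adjusted over the list alone), with Cdh20 (3.14 ± 0.15) higher in skeletal nuclei.

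Motor neuron transcription factors (22 measured, 4 of them class markers) were higher in skeletal nuclei for 12 genes, including Esrrg (3.40 ± 0.16), and in visceral nuclei for 8 (20 adjusted over the list alone). Hox genes, which pattern the body axis, split into 6 higher in skeletal, such as Hoxb6 (1.81 ± 0.30), and 3 in visceral nuclei, such as Hoxc4 (-0.72 ± 0.10), of 18 measured (9 adjusted over the list alone). All 4 inhibitory transmitter genes that passed, of 7 measured, were higher in visceral nuclei (4 adjusted over the list alone), among them Gad2 (-2.43 ± 0.25, 7.29 ± 3.33 against 37.5 ± 4.37 CPM), which makes GABA. Genes linked to amyotrophic lateral sclerosis (27 measured) held 8 higher in skeletal, such as Optn (0.71 ± 0.09) and Nek1 (0.54 ± 0.08), and 5 in visceral nuclei (13 adjusted over the list alone). Immediate early genes, which respond to activity, were higher in visceral nuclei for 5 of 12 (5 adjusted over the list alone), including Fosl2 (-2.69 ± 0.29). Sex-linked genes were 1 higher in skeletal and 3 in visceral nuclei of 10 (3 adjusted over the list alone), with small differences. Slc17a6, the only measured vesicular glutamate transporter gene, was at 3.23 and 3.40 CPM (-0.17 ± 0.32, adjusted p = 0.705). Nuclear-encoded respiratory chain genes were higher in skeletal nuclei for 10 of 18 and in visceral nuclei for 0 (10 adjusted over the list alone), with Uqcrc1 (0.86 ± 0.10) and Atp5a1 (0.76 ± 0.09) in the lead. Set against all other genes by camera, the respiratory chain was the only list of 21 called (adjusted p = 0.049, and adjusted p = 0.626 with an estimated correlation). Its adjusted p was 0.10 without the library block and 0.163 without female replicate 3. Without female replicate 5 the immediate early genes were called by camera as well (adjusted p = 0.00612, and 0.716 with an estimated correlation). The rotation test fry found 17 lists that moved on balance one way and 20 that changed in either direction. The former count was 0 without female replicate 3 and 2 without female replicate 5.

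Cholinergic interneurons, which act within the cord and send no axon to muscle or ganglia, were set against skeletal motor neurons. Skeletal nuclei had more of the calcium-dependent membrane-binding gene Anxa4 (7.74 ± 0.26, 568 ± 173 against 2.69 ± 0.58 CPM). Anxa2 was at 85.1 ± 6.09 CPM against 0 CPM in the interneurons of each library. Skeletal nuclei also had more of the transcription factor genes Creb5 (7.24 ± 0.31) and Isl1 (5.42 ± 0.27), the latter a regulator of motor neuron identity. The protease Pappa (5.70 ± 0.39) and the adhesion molecule Mcam (5.31 ± 0.19) were on the same side. Interneurons had more of the transcription factor gene Ebf2 (-6.21 ± 0.42). The proteoglycan Gpc3 (-7.11 ± 0.34), the collagen Col25a1 (-6.65 ± 0.19), Grm5 (-5.33 ± 0.19) and Plppr1 (-5.27 ± 0.16) were on the same side. Neurofilament genes were higher in skeletal nuclei for 9 of 13 and lower for 2 (12 adjusted over the list alone). Nefm differed by 3.61 ± 0.15, Nefl by 3.37 ± 0.15 and the peripheral nerve filament Prph by 4.70 ± 0.28. The list was called by camera (adjusted p = 0.00603, and adjusted p = 0.491 with an estimated correlation). Motor neuron transcription factors were higher for 14 of 22 and lower for 4 (19 adjusted over the list alone, adjusted p = 0.00359 by camera and 0.491 with an estimated correlation), of which 3 are class markers. All 7 inhibitory transmitter genes were higher in interneurons (7 adjusted over the list alone, adjusted p = 5.7e-05 by camera and 0.313 with an estimated correlation, 0.0362 for the latter without the library block). Of these, 1 is a class marker, and the others included Gad1 (-4.14 ± 0.33), Gad2 (-3.01 ± 0.27) and the vesicular GABA transporter Slc32a1 (-4.46 ± 0.50). The other 18 lists were not called. In all, 4679 genes differed by edgeR, 2425 higher in skeletal nuclei and 2254 in interneurons. With a UMI minimum of 500 the interneuron class held other nuclei, and Ebf2 (-1.57, adjusted p = 0.161), Gad1 (-1.06, adjusted p = 0.173) and Gad2 (adjusted p = 0.9996) were not called. The gene count was 3080 without the library block, 2738 without female replicate 3 and 3113 without female replicate 5. Interneuron cluster 22 (20 nuclei) had 1 interneuron and 2 other-class markers among its 10 leading genes.

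Against visceral motor neurons, interneurons had the BMP receptor Bmpr1b (-7.32 ± 0.35, 0.94 ± 0.51 against 167 ± 45.0 CPM) among their leading genes. The adhesion molecule Dscaml1 (-5.81 ± 0.19), the collagen Col23a1 (-5.49 ± 0.31), the Wnt receptor Ror1 (-5.09 ± 0.22) and Grin3b (-4.50 ± 0.38) were also higher in interneurons. Visceral nuclei had more of Creb5 (7.63 ± 0.31, 776 ± 22.4 against 4.16 ± 1.91 CPM), the relaxin receptor Rxfp1 (7.20 ± 0.78) and the scramblase Plscr4 (6.72 ± 0.38). The actin linker Msn (4.96 ± 0.32), the peptidase Mme (4.76 ± 0.21) and Isl1 (4.65 ± 0.29) were on the same side, and Anxa2 was at 22.7 ± 5.14 CPM against 0 CPM. Ion channel lists leaned to the interneurons. Of 33 voltage-gated potassium channel genes 18 were higher in interneurons, such as Kcnh5 (-2.56 ± 0.13) and Kcnma1 (-1.17 ± 0.08), and 5 in visceral nuclei (25 adjusted over the list alone). The list had adjusted p = 0.00088 by camera and 0.215 with an estimated correlation. Of 23 sodium, calcium and HCN channel genes 10 were higher in interneurons, such as Scn1a (-1.60 ± 0.11), and 4 in visceral nuclei, such as Cacna1e (2.47 ± 0.16), with 16 adjusted over the list alone. Their adjusted p by camera was 0.0277 (0.215 with an estimated correlation, 0.053 without female replicate 3 and 0.0575 without female replicate 5).

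Neurofilament genes were higher in visceral nuclei than in interneurons for 7 of 13 and lower for 0 (7 adjusted over the list alone, adjusted p = 0.00088 by camera and 0.215 with an estimated correlation). Prph differed by 4.11 ± 0.28, Nefl by 2.89 ± 0.16 and Nefm by 2.18 ± 0.15. Motor neuron transcription factors were 10 higher and 5 lower of 22, including 1 class marker (17 adjusted over the list alone), with Nr2f2 at 4.61 ± 0.21. Camera gave them adjusted p = 0.0248, 0.285 with an estimated correlation and 0.0627 without female replicate 5. Inhibitory transmitter genes were higher in interneurons for 5 of 7 (7 adjusted over the list alone, adjusted p = 0.000579 by camera and 0.215 with an estimated correlation), such as Gad1 (-5.15 ± 0.34). Respiratory chain genes were higher in interneurons for 6 of 18 and in visceral nuclei for 0 (9 adjusted over the list alone). Uqcrc1 was among them (-0.67 ± 0.11), and the list had adjusted p = 0.00189 by camera and 0.215 with an estimated correlation. Hox genes were higher in interneurons for 8 of 18, such as Hoxb4 (-3.80 ± 0.26), and lower for 5 (13 adjusted over the list alone). The Hox list and the cholinergic list were called by camera only without the library block (adjusted p = 0.0245 and 0.0401). With an estimated correlation that fit gave adjusted p = 0.316 and 0.19. Glutamate receptors were called by camera only without male replicate 4 (adjusted p = 0.0304, and 0.33 with an estimated correlation). Immediate early genes were called only without female replicate 5 (adjusted p = 0.00156, and 0.429 with an estimated correlation). By edgeR 3417 genes differed, 1699 higher in visceral nuclei and 1718 in interneurons. The count was 2108 without the library block, 1590 without female replicate 3 and 2174 without female replicate 5.

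Within skeletal nuclei, alpha-like and gamma-like motor neurons were compared. Alpha-like nuclei had more of Mrvi1 (6.61 ± 0.28, 65.3 ± 6.16 against 0.67 ± 0.25 CPM), whose protein binds calcium release channels, and of the T-type calcium channel Cacna1g (5.21 ± 0.36). The synaptic vesicle gene Sv2b was also higher there (4.96 ± 0.16, 329 ± 70.9 against 11.5 ± 6.97 CPM), as were the transcription factor genes Maf (4.69 ± 0.30) and Glis3 (4.39 ± 0.14), and the sodium-activated potassium channel Kcnt2 (4.01 ± 0.18). Gamma-like nuclei had more of the metalloproteinase Adamts16 (-5.77 ± 0.21), the calcium channel adaptor Stac (-5.64 ± 0.16, 4.48 ± 1.61 against 212 ± 19.4 CPM) and the zinc finger gene Zfp536 (-4.79 ± 0.14). The polarity gene Pard3b (-4.75 ± 0.12) and the TGF-beta binding gene Ltbp1 (-4.33 ± 0.17) were also higher in gamma-like nuclei. Among 32 voltage-gated potassium channel genes 10 were higher in alpha-like and 6 in gamma-like nuclei (19 adjusted over the list alone). Kcnb2 (2.19 ± 0.08) was on the alpha-like side, and Kcnc1, a channel of fast-firing neurons (-2.44 ± 0.12), and Kcnip1 (-1.99 ± 0.11) were on the gamma-like side. Axon guidance genes split into 12 and 10 of 30 (22 adjusted over the list alone). The netrin receptor Unc5d (2.55 ± 0.11) was higher in alpha-like nuclei, and the semaphorin Sema3c (-3.39 ± 0.14) and its receptor Nrp2 (-2.48 ± 0.13) in gamma-like nuclei. Nrp2 was not high in all gamma-like nuclei. In gamma-like cluster 2 (151 nuclei) it was at 1 ± 0.9 CPM, against 164.9 ± 59.4 CPM in the other skeletal nuclei. GABA and glycine receptor genes split into 4 and 9 of 17 (14 adjusted over the list alone), with Gabra2 (1.66 ± 0.12) and Gabrg3 (-2.38 ± 0.13) on opposite sides. Monoamine receptors were higher in alpha-like nuclei for 1 of 9, Adra1a for noradrenaline (2.85 ± 0.15), and in gamma-like nuclei for 5 (8 adjusted over the list alone). Among the latter, of which 1 is a gamma marker, was the serotonin receptor Htr2a (-1.85 ± 0.10). Neuropeptide receptors (8 measured, including 1 alpha marker) split into 3 and 4 (7 adjusted over the list alone), with Tacr1 for substance P (3.64 ± 0.31) and Trhr for thyrotropin-releasing hormone (5.06 ± 0.33) higher in alpha-like nuclei. Neuropeptides split into 2 and 1 of 5 (3 adjusted over the list alone), with Nts (-4.67 ± 0.44) higher in gamma-like nuclei.

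**Figure D3:**
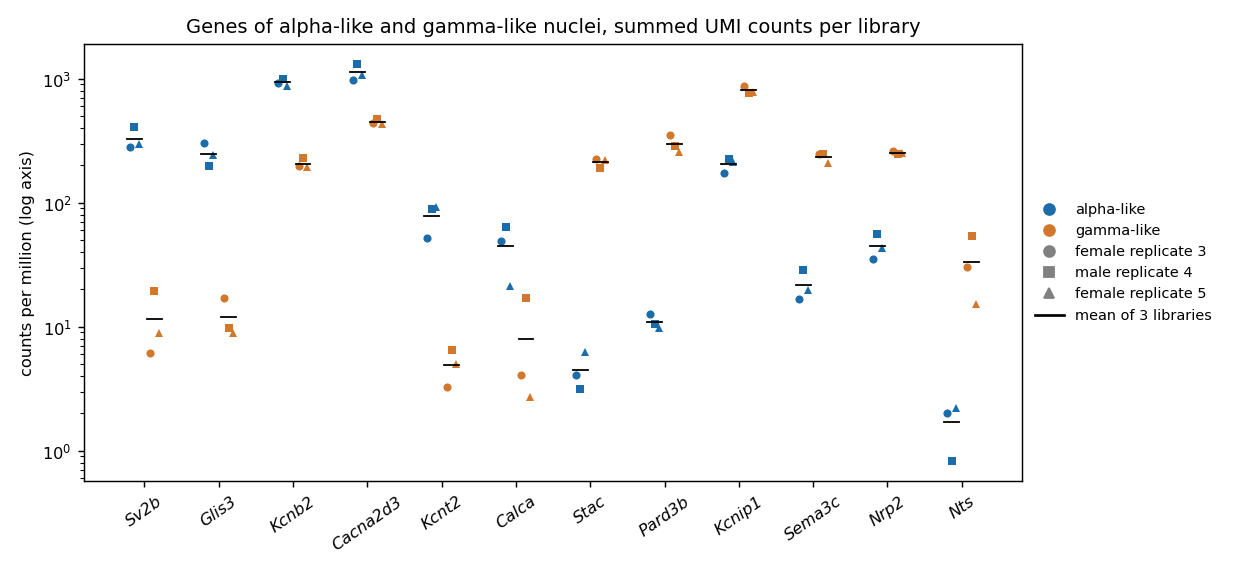
Expression of 12 named genes in alpha-like and gamma-like skeletal nuclei. The y axis is CPM on a log scale, colour marks the class, marker shape the library and the black line the mean of 3 libraries. Sv2b was at 329 CPM in alpha-like against 11.5 CPM in gamma-like nuclei, and Stac at 4.48 against 212 CPM.

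Of 26 genes linked to amyotrophic lateral sclerosis 6 were higher in alpha-like nuclei, including Tbk1 (0.48 ± 0.12), and 0 in gamma-like nuclei (6 adjusted over the list alone). Camera did not call this list. Tbk1 was not called without female replicate 3 (adjusted p = 0.0913) or without female replicate 5 (adjusted p = 0.121). Respiratory chain genes were lower in alpha-like nuclei for 2 of 18, Ndufs1 (-0.45 ± 0.11) and Sdha (-0.49 ± 0.12), and higher for 0 (2 adjusted over the list alone). The respiratory chain was the only list of 21 called by camera (adjusted p = 0.0231, and adjusted p = 0.767 with an estimated correlation). Its adjusted p was 0.0687 without the library block, 0.0923 without female replicate 3 and 0.0843 without female replicate 5. Ndufs1 was not called without female replicate 3 (adjusted p = 0.0593) and Sdha not without female replicate 5 (adjusted p = 0.15). DESeq2 (log2 fold changes of 0.47, -0.46 and -0.50) and the fit without the library block (0.48, -0.46 and -0.49) called none of Tbk1, Ndufs1 and Sdha. In clusters with at least 10 nuclei in each library, a fit added later, Ndufs1 (-0.46, adjusted p = 0.0577) and Sdha (-0.46, adjusted p = 0.0506) were not called. With edgeR, 2671 of 11558 genes differed, 1432 higher in alpha-like and 1239 in gamma-like nuclei. DESeq2 called 1305. The count was 1273 without the library block and 1644 without female replicate 5. Different clusters held the alpha-like class in different libraries. Of the 140, 84 and 29 nuclei of clusters 3, 4 and 8, 136, 65 and 24 came from the male library, and of the 54 nuclei of cluster 6, 0 did. Gamma-like nuclei formed 3 clusters, of which 2 had at least 20 nuclei in each library. Cluster 1 (173 nuclei, 1723 genes called against the other skeletal nuclei) was marked by the Wnt antagonist Dkk2 (125.7 ± 18.3 against 6.3 ± 6.8 CPM) and held Nts at 57.9 ± 29.5 against 4.1 ± 0.8 CPM. Cluster 2 (151 nuclei, 1621 genes called) was marked by the adhesion gene Cntnap3 (98.4 ± 38.2 against 5.7 ± 5.7 CPM) and the receptor gene Gpr149 (334.2 ± 130.3 against 32.2 ± 19.6 CPM).

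Visceral motor neurons formed 10 clusters with at least 20 nuclei in each library, and neuropeptide genes differed between them. Cluster 1 (200 nuclei) was marked by Cartpt, the precursor of the CART peptide (322.1 ± 117.3 against 26.4 ± 9.4 CPM in the other visceral nuclei), with Ccbe1 and Chodl. Cluster 2 (178 nuclei) was marked by the somatostatin gene Sst (194.3 ± 46 against 1.7 ± 0.2 CPM), Slc26a7 and Penk (541.6 ± 93.8 against 9.4 ± 4.6 CPM). It was low in the PACAP precursor Adcyap1 (1.0 ± 1.1 against 41.7 ± 14.7 CPM). The gastrin-releasing peptide gene Grp (29.8 ± 34 against 0.8 ± 1.5 CPM) was also higher there. Cluster 3 (173 nuclei) was marked by Agmo, Nfib and Tenm2 and was high in the neurotensin gene Nts (139.9 ± 48.5 against 6.2 ± 0.8 CPM). Among these 10 clusters, cluster 4 (163 nuclei, marked by Mdga1, Adamts18 and St6galnac5) had the most of the nitric oxide synthase gene Nos1 (587.6 ± 55.6 against 250.2 ± 37.2 CPM). Cluster 13 (47 nuclei) had fewer than 20 nuclei in a library and was not tested. With libraries pooled, Nos1 was at 920.5 CPM in cluster 13 and 608.9 CPM in cluster 4. Cluster 5 (123 nuclei, marked by Synpr, Postn and Pkib) had the most of the secretory granule gene Vgf (84.7 ± 21 against 22.2 ± 2.9 CPM). Nos1 was also higher than in the other visceral nuclei in clusters 7 (113 nuclei, Gpc3, Rorb and Ptprk), 8 (89 nuclei, Ndst4, Cdh18 and Gas7) and 9 (84 nuclei, Runx2, C130060K24Rik and Unc13c). It was lower in clusters 1, 2, 3 and 5, and in cluster 11 (63 nuclei, Fam19a1, Dcc and Fam19a2, 87.5 ± 20.6 against 305.7 ± 47.8 CPM). It was not called in cluster 10 (83 nuclei, Sema5a, Gm21949 and Arhgap24), at 331.8 ± 63.9 against 281 ± 47.7 CPM. Between 623 (cluster 10) and 2575 (cluster 2) genes were called per cluster by edgeR. They were called from counts that also defined the clusters, so these genes describe the clusters and are no independent finding.

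**Figure D4:**
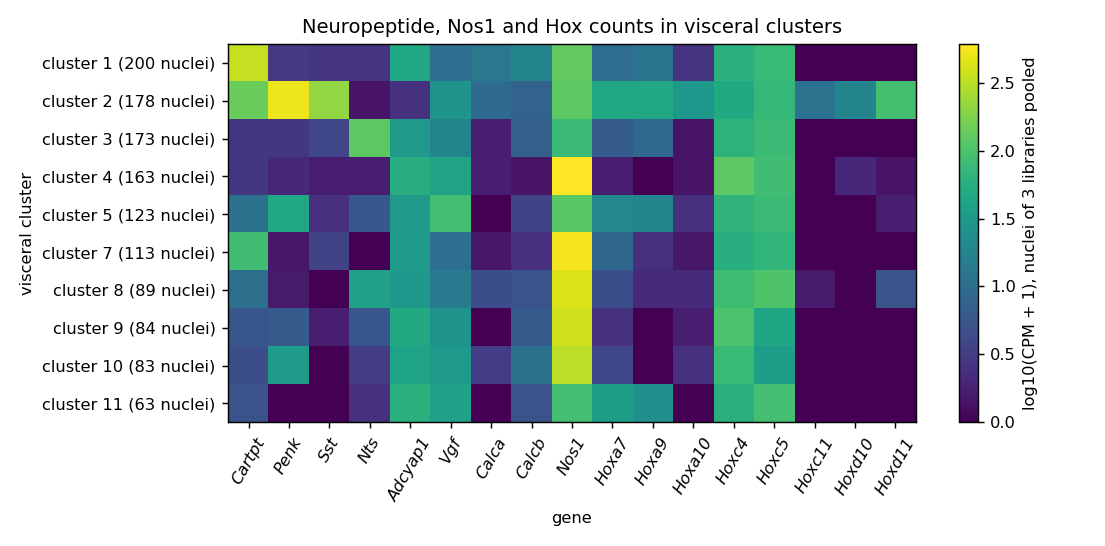
Neuropeptide, Nos1 and Hox genes in the 10 visceral clusters. Colour gives the log10 of CPM + 1, with the nuclei of each cluster pooled over the 3 libraries. Sst and Penk were bright in cluster 2, Nts in cluster 3, Cartpt in cluster 1 and Hoxd11 in cluster 2. Clusters with fewer than 20 nuclei in a library are not shown, among them cluster 6 (Hoxd11 at 99.4 CPM).

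Single Hox genes also differed between visceral clusters, a reading chosen after the clusters were seen. The genes named are a selection, and the Hox list was not tested between clusters. In cluster 2, Hoxd11, a gene of the caudal cord (chromosome 2, 74679557 to 74687016, plus strand, mm10), was at 90.9 ± 3.2 against 7.0 ± 3.1 CPM. Hoxd10 (17 against 1.1 CPM), Hoxa10 (27.2 against 3.6 CPM), Hoxc11 (11.5 against 1.4 CPM) and Hoxa9 (35.3 against 7.8 CPM) were on the same side. Hoxc4 was lower there (44 against 75 CPM). The pattern was not particular to cluster 2. Cluster 6 (116 nuclei) had 19 nuclei in the male library, under the limit of 20, and was not tested. With libraries pooled, Hoxd11 was at 99.4 CPM in cluster 6 and 92.1 CPM in cluster 2. Sst (6.2 CPM) and Penk (16 CPM) were low in cluster 6. Cluster 4 had more Hoxc4, a gene of more rostral cord (116.8 against 64.7 CPM), and Hoxa9 was at 0 against 12.2 CPM there.

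Female and male libraries were compared within each motor neuron class. In skeletal nuclei Xist, which silences 1 X chromosome in females, was at 934 and 940 CPM in the female libraries and 0.67 CPM in the male library. The Y-linked genes Uty (0.68 and 2.05 against 151 CPM), Eif2s3y, Kdm5d and Ddx3y were higher in the male library. Ddx3y was not called by DESeq2 (-6.24, adjusted p = 0.52) or within alpha-like nuclei alone (-5.39, adjusted p = 0.051). Beside these, Kcnd2, a transient potassium channel, was at 1744.5 and 1642 CPM in female against 549 CPM in male nuclei (log2 fold change 1.63 ± 0.10). Cacna2d1, a calcium channel subunit, was also higher in the female libraries (816 and 806 against 246 CPM, 1.72 ± 0.12). Opcml (1.45 ± 0.10), Kirrel3 (1.71 ± 0.13) and Plekhg1 (2.22 ± 0.18) followed, and Parm1 (-2.45 ± 0.19) was higher in the male library. Between alpha-like and gamma-like nuclei, Kcnd2 (-2.60 ± 0.23), Cacna2d1 (-2.77 ± 0.25), Opcml (-2.91 ± 0.14), Kirrel3 (-3.60 ± 0.14) and Plekhg1 (-4.66 ± 0.20) were higher in gamma-like nuclei, the class with the larger share in the female libraries. By edgeR 737 of 14365 genes differed in skeletal nuclei, 345 higher in the female and 392 in the male libraries, of which 489 also differed between alpha-like and gamma-like nuclei. DESeq2 called 374, and the count was 256 with doublets kept. In fits added after the data were seen it was 25 within alpha-like nuclei, 172 within gamma-like nuclei (115 of them among the 737) and 5 (median of 20 draws) with male nuclei drawn to the female alpha-like share. Kcnd2 and Cacna2d1 were called within alpha-like nuclei alone but not within gamma-like nuclei alone (0.19, adjusted p = 0.565, and 0.23, adjusted p = 0.513), and Opcml and Kirrel3 in neither. Plekhg1, at 1.69 within alpha-like nuclei alone, was not called there. Most male alpha-like nuclei lay in clusters 3 and 4, and most female ones in clusters 5 and 6.

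In visceral nuclei, by contrast, 4 of 15369 genes were called by edgeR, and all were sex-linked. They were Xist (717 and 810 CPM in female against 1.17 CPM in male nuclei), Uty, Eif2s3y (0 and 0 against 115 CPM) and Kdm5d (0 and 0 against 72.8 CPM). At an unadjusted p under 0.05 there were 1695 genes, and DESeq2 called 51. The count was 65 with no filter on low counts and 7 with doublets kept. Of the genes that escape X inactivation, Kdm6a (0.88 ± 0.15, adjusted p = 0.404) and Kdm5c (0.74 ± 0.16, adjusted p = 0.416) missed the threshold, as did the Y-linked Ddx3y (-6.01 ± 0.39, adjusted p = 0.0573). Ddx3y was called with UMI minimums of 500 and 2000 (adjusted p = 0.0398 and 0.0179), doublets kept (0.00577), relative log expression scaling (0.0347) and no filter (1.88e-05), at -6.06 to -5.95. An interaction test of the sex difference between skeletal and visceral nuclei called 727 of 14116 genes, of which 516 also differed between alpha-like and gamma-like nuclei. Both comparisons rest on 1 male library, so sex and library cannot be told apart. With 1 residual degree of freedom, what could be called was limited. In simulated counts 31.3% (skeletal) and 30.9% (visceral) of genes changed 2-fold were recovered. That simulation gave genes of like expression the same spread. It therefore cannot show that the skeletal and visceral fits were equally able to call genes, and the difference in counts may lie in the fits. Visceral sub-cluster 12 (59 nuclei) had 0 visceral markers and 1 marker of another class, Reln, among its 10 leading genes.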

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

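The tests chosen only after the result was seen were the fits within alpha-like and within gamma-like nuclei, the overlap of the interaction test with the alpha-like genes and the counts of other splits of the class sums. The draws to the female alpha-like share, thinning, the comparison of genes inside other genes and the count of nuclei with both kinds of transmitter gene were also chosen after their patterns were seen, but before their own results were. The 2 interaction tests are given here because a difference between classes was not the same in the male library as in the female ones, and the added sequences because they are a signal outside the genes compared above.

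The difference between skeletal and visceral nuclei was not the same in the male and the female libraries for 727 of 14116 genes by edgeR's interaction test (2306 at an unadjusted p under 0.05), led by Cacna2d1 (-2.03). Of the 727, 516 also differed between alpha-like and gamma-like nuclei, Cacna2d1 among them (-2.77), and 492 of these (95.3%) went in the direction that the larger alpha-like share of the male library gives. The alpha-like against gamma-like difference was not the same for 116 of 11558 genes (1081 unadjusted), led by Kcnd2 (-1.40). Both rest on 1 male library, so neither shows a difference between the sexes.

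In skeletal nuclei 737 genes were called between sexes, and 489 of them also differed between alpha-like and gamma-like nuclei, 467 of these (95.5%) in the direction that the larger alpha-like share of the male library gives. With male nuclei drawn to the female alpha-like share, a median of 5 genes was called over 20 draws (range 4 to 58), against 575 (286 to 745) in draws of the same number of nuclei at the male share, so the share of alpha-like nuclei may account for most of the count. The draws also took fewer male alpha-like nuclei (44 against 100), most of which lay in clusters 3 and 4, held mainly by the male library. They therefore cannot tell the share from the clusters. Within gamma-like nuclei alone 172 genes were called, and 115 of these were among the 737 with the same direction. The alpha-like share does not enter that fit and does not account for these calls. Gamma-like cluster 7 held 18, 4 and 17 nuclei per library, so clusters and library stay mixed there too. Thinning the 3 sums to the smallest total left 547 genes (428 to 892 over 5 draws), a spread that cannot tell whether depth plays a part. Sex itself stays open and untested, because it cannot be told apart from the single male library.

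Slc18a3 had no UMI in any barcode. Of 372 protein-coding genes that lie inside another protein-coding gene on the same strand, 371 (99.7%) had 0 UMIs, against 62 of 534 (11.6%) inside a gene on the opposite strand (ratio 8.59, two-sided Fisher's exact p = 6.4e-187). A candidate explanation is that the counting left out reads that matched both genes, which would apply to Slc18a3 inside Chat and to Hoxa4, Hoxa5, Hoxc6, Hoxc8, Hoxc9 and Hoxd4 inside other Hox genes. No biological explanation was tested, and the annotation used for the counts was not seen.

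Clusters that held both Slc17a6 and the inhibitory genes Slc6a5 or Gad2 made up 3144 nuclei, with median UMIs 1.59, 1.90 and 1.59 times the mean of the excitatory-like and inhibitory-like medians. Within these clusters, 173 nuclei had UMIs of both kinds, where independent detection would give 622.8, a ratio of 0.278 (0.245 to 0.313 over 1000 resamples). Clusters made up mainly of doublets of an excitatory and an inhibitory nucleus would give a ratio of about 1 or more. The ratio argues against doublets as the main content of these clusters. It cannot exclude doublets among the 173 nuclei with both kinds. Their median UMIs were 20015, 14859 and 14087, against 17726, 11743.5 and 11128 in nuclei with 1 kind. Separate excitatory and inhibitory nuclei joined in 1 cluster are consistent with the ratio of 0.278, and what sets the higher UMI counts stays open.

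For each comparison of classes there are 10 ways to divide the 6 library sums into groups of 3, too few for a share under 0.05. The classes were also clustered from these same counts. The real division was thus bound to call many genes, and the counts that follow cannot weigh chance. The real division called 6065 genes for skeletal against visceral nuclei, 3909 for skeletal nuclei against interneurons, 3659 for visceral nuclei against interneurons and 2671 for alpha-like against gamma-like nuclei, each in a fit of those 6 sums, and the highest of the other divisions called 0 in each comparison, so that 1 of 10 reached the real count.

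The Cre sequence had 36, 15 and 9 UMIs in female replicate 3, male replicate 4 and female replicate 5, EGFP had 6 in female replicate 3 and tdTomato 7 in male replicate 4, against a floor of 3 counts per library. The human SOD1 sequence had 30 UMIs in female replicate 3 and 1298 in female replicate 5, the latter in 1263 barcodes, of which 1233 had under 100 UMIs in total and 2 at least 1000.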

How the results depend on the processing

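The fits within alpha-like or gamma-like nuclei alone, the draws to the female alpha-like share, the fit of skeletal clusters with at least 10 nuclei in each library, the nuclei per library under other limits and the class shares under other settings were chosen only after the data were seen. Counts of genes called stayed within 1.5 times the reported value except where given here, and the cause was not tested unless named. Without the library as a replicate block, which pairs the classes of 1 library, the counts were 4195 (skeletal against visceral), 3080 (skeletal against interneurons), 2108 (visceral against interneurons) and 1273 (alpha-like against gamma-like) in place of 6401, 4679, 3417 and 2671, and the block changed no other count by over 1.5 times. Leaving out 1 library gave 4243 to 6696, 2738 to 4503, 1590 to 3842 and 1644 to 2777 genes, lowest without female replicate 3 in the comparisons of 3 classes and without female replicate 5 between alpha-like and gamma-like nuclei, in fits with fewer samples. DESeq2 called 1305 genes between alpha-like and gamma-like nuclei. Between sexes in skeletal nuclei DESeq2 called 374 of the reported 737, the fit with doublets kept 256, the fits within alpha-like and gamma-like nuclei alone 25 and 172, and the draws to the female share a median of 5. In visceral nuclei DESeq2 called 51 in place of 4, the fit with no filter 65 and the fit with doublets kept 7. No fit between sexes without 1 library had replicates in both groups and residual degrees of freedom, so none was tested. With clusters made from 1 part of the UMIs and tests on the other, 5199, 3475, 2525 and 1898 genes were called in the comparisons of classes. The skeletal clusters with at least 10 nuclei in each library gave 2122 genes between alpha-like and gamma-like nuclei, with 1652 of the reported 2671 in the same direction and 13 in the opposite direction. With a UMI minimum of 500, 27 (skeletal) and 28 (visceral) of the genes reported against interneurons were called in the opposite direction. Leiden resolutions of 0.5 and 2 gave the same alpha-like and gamma-like nuclei, so that alternative tested nothing. Of 84 list tests camera called 11, and 0 with an estimated correlation, and 8 to 12 with 1 library left out. Without the library block 1 was called with an estimated correlation. Fry called 48 lists on balance in 1 direction, but 8 without female replicate 3, 39 without male replicate 4 and 19 without female replicate 5. The cholinergic share was 24.7% to 31.2% under other UMI minimums, with doublets kept or at other resolutions, and 24.2% to 35.4% with 1 library left out. The interneuron share of cholinergic nuclei was 7.79% with a UMI minimum of 500 in place of 14.6%, and the cause was not tested. The skeletal, visceral and alpha-like shares moved by less than 1 SD under these settings. Nuclei per library averaged 3632 ± 1922.2 (SD), and 3277 to 3882.7 under other limits. Visceral clusters numbered 8 with a UMI minimum of 500 and 9 at resolutions of 0.5 and 2. Without a filter the median log2 fold change of all genes was 0.121 (skeletal) and 0.118 (visceral) in the comparisons with interneurons, in place of -0.001 and 0.002. Of the values of named genes under alternatives, 1623 kept their direction and side of the threshold, 24 lost and 5 gained a call. In 1 case the direction turned: Gad2 between skeletal nuclei and interneurons had a log2 fold change of 0.00 with a UMI minimum of 500, where the interneuron class held 53, 100 and 36 nuclei. Depth limits the low genes most, since a count of 0 in a library sum allows up to 3 counts.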
